A study of Homo with 12 samples.

How the data were processed

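RNA from RKO, an established human colorectal cancer cell line, was sequenced in 12 libraries of 3 replicates in each of 4 groups. Cells were exposed to the DHODH inhibitor HL6 or to DMSO, the vehicle, or carried an shRNA against DHODH (shDHODH) or a non-targeting shRNA (shNT). Per the labels' protocols, polyadenylated RNA was selected before library construction; the sequencing instrument and read layout are not given in the sources used here. The labels describe RNA extraction in more than 1 way. The series' design text calls the replicates biological, without saying whether they were separate cultures or days.

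The authors deposited a table of raw read counts per gene for each pair of groups, and every value analysed here comes from those counts. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.10a, SAMtools 1.16, featureCounts 2.0.3 from Subread, Salmon and DESeq2 1.40.0 were used, with genome build GRCh38.p13. The notes give neither the order of these tools nor the annotation release, and whether counting used strand is not given in the sources used here. The tables list different gene sets: 19931 genes in the inhibitor table, with non-coding and mitochondrially encoded genes, and 14618 in the knockdown table, nearly all protein-coding. Reads of antisense, overlapping or near-identical genes, such as histone genes, cannot be told apart with certainty in such counts. The values are relative, so a change in total RNA per cell would not be seen.

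Libraries were grouped by title and library name. The treatment label of HL6 replicates 2 and 3 names HL7 and HL8 instead of HL6, so a fit with HL6 replicate 1 alone was among the alternatives. The inhibitor and knockdown libraries carry different day labels (day 1 and day 0) and were fitted separately. No column of values was left unmapped.

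Library totals ran from 38159898 to 41666499 counts. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.58 to 94.0. That is more than repeat counting of the same library would give, but it does not show separate cultures. All 12 were counted as separate samples because the series' design text calls the replicates biological. Intervals and floors below cover counting error only. P-values measure the spread between these replicates.

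Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes passing filterByExpr (minimum count 10, minimum total 15), TMM scaling, and the two-sided quasi-likelihood test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Adjusted p-values of single genes are from this test. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are given as CPM from edgeR, read counts scaled to a common TMM-scaled library size, and means are given ± SD over 3 libraries. For a gene without a control count, the fold is a lower bound against a floor of 3 counts over the control group; with 1 to 3 control counts, the ratio has a 95% exact counting interval.

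The difference between the inhibitor and knockdown effects was tested as an interaction in a 4-group edgeR model over genes in both tables, matched on NCBI gene number. Gene lists (45, with at least 3 tested members) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists, and again with the correlation estimated from the data. Of 973 list genes, 924 were found in the inhibitor table and 914 in the knockdown table. A RefSeq gene table of assembly GRCh38.p14 served only to match names; because the builds differ, no coordinates or gene lengths were used.

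Lists, tests and the rule for named genes were fixed before the data were examined. The rule names DHODH first; then per comparison the 10 largest log2 fold changes in each direction among genes past the threshold with a mean count of at least 50, no overlap between groups and an official symbol; up to 4 members of smallest p per described list; HEXIM1, CAD, UMPS, PIK3CA, MYC, CDKN1A, GDF15, ATF4, GPX4 and SLC7A11; and for the difference, the 5 genes of smallest p in each direction.

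The fits were tested on simulated counts with most genes left unchanged, so change as widespread as in the data was not simulated. Changes of 4-fold, 2-fold and 1.5-fold were put into 66 or 67 known genes each. Recovery is given as a share of those known genes that passed the filter again in the simulated counts. For the inhibitor comparison (13636 genes), 98.5%, 60% and 40.3% of them were recovered; for the knockdown (11864 genes), 100%, 87.9% and 73.1%; for the difference (12282 genes), 83.3%, 75.8% and 34.3%. Alternatives were DESeq2 1.42.0, RLE size factors, no filter or a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library in turn, 1 fit over all 12 libraries, and for lists fry and the estimated correlation. Alternatives that concern a pseudocount were not applicable to counts. Figures were drawn with matplotlib 3.10.9.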

Results

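The series asks what happens to the transcriptome of PIK3CA-mutant colorectal cancer cells when dihydroorotate dehydrogenase (DHODH), the mitochondrial enzyme of de novo pyrimidine synthesis, is inhibited or depleted. RKO cells were profiled by polyadenylated RNA sequencing in 12 libraries: 3 each for HL6 and DMSO, and 3 each for shDHODH and shNT. Library totals were 39430012 to 40678647 counts in the inhibitor experiment and 38159898 to 41666499 in the knockdown experiment.

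DHODH mRNA (NCBI gene symbol DHODH) was measured first, since it checks the shRNA labels. It stood at 4.42 ± 1.04 CPM (SD) under shDHODH and 24.9 ± 3.04 CPM under shNT, lower in all 3 shDHODH libraries than in any shNT library, a log2 fold change of -2.49 ± 0.16 (SE, n = 3 per group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.0e-10). Under HL6, which is described as acting on the protein, DHODH mRNA was 11.4 to 14.2 CPM in the 3 libraries against 18.6 to 24.1 CPM under DMSO, a log2 fold change of -0.74 ± 0.18 (edgeR, adjusted p = 0.00144). The fall was larger under the knockdown, by 1.71 ± 0.24 on the log2 scale (edgeR interaction, adjusted p = 1.2e-05).

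**Figure D1:**
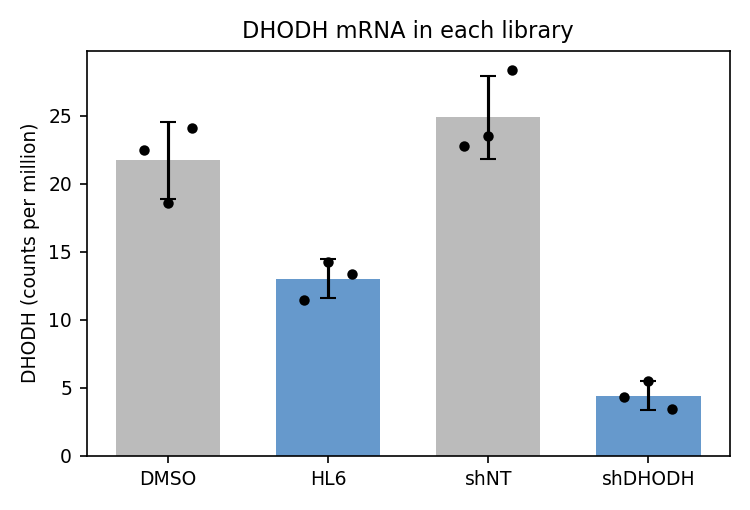
DHODH in CPM (linear axis from 0) in each group; bars are means, error bars SD and points the 3 libraries. All 3 shDHODH libraries lie below all 3 shNT libraries, with means of 4.42 and 24.9.

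The first comparison asks what the inhibitor changed. Under HL6, interferon-stimulated genes and targets of the tumour suppressor p53 rose, while genes of DNA replication, ribosome assembly, purine and deoxynucleotide supply and heat shock fell. Of 33 tested type I interferon response genes, 30 rose, with a median log2 fold change of 2.19; IRF9, part of the transcription factor complex downstream of interferon receptors, rose 24.4-fold and OAS1, a sensor of double-stranded RNA, 23.0-fold. Of 32 p53 targets, 30 rose (median 1.76). GDF15, a stress-induced cytokine, went from 3.32 to 380 CPM (log2 fold change 6.84 ± 0.16), and CDKN1A, the cell cycle inhibitor p21, from 260 to 684 CPM, 2.63-fold higher. Of 39 DNA replication genes, 35 fell (median -1.31), among them the helicase subunits MCM5 (-2.20 ± 0.12) and MCM4 (-1.87 ± 0.12).

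In total 4269 genes were higher and 3675 lower among 13636 tested (edgeR, adjusted p below 0.05), and 2531 and 1281 of these changed at least 2-fold. The groups did not overlap in CPM for 61.9% of genes, against 10% by chance. Of the 10 largest rises, 9 were of genes with no count in any DMSO library. LCE1B, a late cornified envelope gene, reached 35.3 CPM, at least 1338-fold higher. PDE6G was at least 287-fold higher, GRHL3, an epidermal transcription factor, at least 235-fold, TMEM40 at least 234-fold, LRATD1 at least 227-fold, CYP4F2 at least 204-fold, CNN1 at least 200-fold, CSMD3 at least 158-fold and CPA4 at least 149-fold. AKR1B10, an aldo-keto reductase with 1 count under DMSO, had a ratio of 1664 (95% interval 298 to 65759). The largest falls were of the histone gene H2BC9 (-4.09 ± 0.29), the non-coding DLEU2 (-3.49 ± 0.36), DANCR (-3.08 ± 0.13) and SNHG10 (-2.95 ± 0.23), FADS2, a fatty acid desaturase (-2.99 ± 0.18), H2AC20 (-2.95 ± 0.30), CLDND2 (-2.78 ± 0.39), the nucleolar UTP20 (-2.65 ± 0.37), AMMECR1 (-2.63 ± 0.36) and the splicing factor SRSF1 (-2.59 ± 0.13). Histone genes and transcripts that overlap others are uncertain in counts of unstated strand.

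By camera, other splits of the 6 libraries gave up to 28 lists, but they keep part of the treatment contrast. In the real groups, 31 of 45 lists passed the threshold, 16 up and 15 down. With an estimated correlation 8 did: type I interferon and p53 targets upward (adjusted p = 0.00557 each), and downward ribosome biogenesis and MYC targets (0.0132 each), DNA replication (0.0201), heat shock (0.0329), dNTP supply (0.0335) and purine synthesis (0.0409). Counts of members adjusted over the list alone equalled those over all genes for 7 of these lists; for MYC targets they were 17 against 16 of 19. Of 40 ribosome biogenesis genes, 37 fell (median -1.12), including the nucleolar proteins NCL by 4.63-fold and NOP56 by 3.90-fold. Of 13 heat shock genes, 10 fell (median -1.55), including the mitochondrial chaperonin HSPD1 by 4.77-fold and HSPA8 by 3.69-fold. All 14 purine synthesis genes fell (median -1.01), with PAICS lower by 3.35-fold and PFAS at -1.63, and of 14 dNTP supply genes 11 fell and 1 rose, with the ribonucleotide reductase subunit RRM2 lower by 3.43-fold.

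Several other lists passed with the preset correlation and not with an estimated one. Of 27 genes of the ATF4 integrated stress response, 20 rose and 2 fell (median 0.97; adjusted p = 0.0768 with an estimated correlation), with ATF3 up 15.6-fold and DDIT3 up 6.59-fold. Of 74 cytosolic ribosomal protein genes, 63 fell and none rose (median -0.71; adjusted p = 0.232 with an estimated correlation), with RPL6 at -1.99 and RPL23 at -1.52. Of 40 mitosis genes, 28 fell and 2 rose (median -0.79; adjusted p = 0.207 with an estimated correlation), with the checkpoint gene MAD2L1 at -1.59 and the kinase PLK1 at -1.27. FOXO targets rose in 16 of 20 cases (median 1.00; adjusted p = 0.163 with an estimated correlation), with TXNIP 8.00-fold higher and PIK3IP1 at 3.64. Members adjusted over the list alone were 20 and 2 for ATF4, 63 for ribosomal proteins, 29 and 2 for mitosis, and 17 risen and 1 fallen for FOXO targets.

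Of 5 tested genes of de novo pyrimidine synthesis, DHODH among them, 3 fell, and 4 did when adjusted over the list alone (median -0.74; camera, adjusted p = 0.0223, and adjusted p = 0.207 with an estimated correlation). CTPS1, which makes CTP, fell most (-1.55 ± 0.12), and UMPS, which makes UMP, also fell (-0.80 ± 0.12). CAD, which starts the pathway, was at -0.33 ± 0.14 (edgeR, adjusted p = 0.057). PIK3CA was at -0.60 ± 0.29 (edgeR, adjusted p = 0.0877) and the cystine transporter SLC7A11 at -0.07 ± 0.37 (edgeR, adjusted p = 0.881), neither past the threshold. ATF4 (0.97 ± 0.12) and GPX4, which detoxifies lipid peroxides (0.96 ± 0.13), rose; MYC (-0.30 ± 0.11) and the transcription elongation inhibitor HEXIM1 (-0.40 ± 0.12) fell. The HL6 libraries also held more detected genes (17173 to 17313, against 15227 to 15306 under DMSO) and a larger share of mitochondrially encoded mRNA (9.12% to 9.92%, against 6.34% to 7.44%). Of 13 mitochondrially encoded mRNAs, however, 5 rose and 3 fell, and the list did not pass (median 0.14, camera, adjusted p = 0.721). Markers of other cell types rose: all 4 tested fibroblast markers, all 4 endothelial, all 3 neuroendocrine and 3 of 4 leukocyte markers. These are the ones that passed the count filter, of 12, 10, 10 and 14 listed. Their levels ranged widely, from COL1A1 at 1.63 CPM against 0.0527 and ESAM at 39.95 against 5.42 to ENO2 at 310 against 150 and CD68 at 1331 against 942. A marker with almost no DMSO counts passed the filter only through its HL6 counts, so its direction was fixed in advance. The adjusted p with an estimated correlation was 0.207 for the fibroblast and endothelial lists and 0.170 for the neuroendocrine list, and the leukocyte list did not pass with either correlation. With HL6 replicate 1 alone, the library whose treatment label also reads HL6, 2758 genes were higher and 1965 lower, with the spread taken from the DMSO libraries.

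The second comparison asks what depletion of DHODH changed. Interferon, p53, antigen presentation and lysosomal genes rose with the knockdown, and cell cycle and lipid synthesis genes fell. Of 32 p53 targets, 28 rose and 2 fell (median 1.19), with GDF15 from 7.45 to 213 CPM (4.84 ± 0.08) and CDKN1A from 271 to 948 CPM (1.80 ± 0.06). Of 33 interferon genes, 30 rose (median 1.73), with IFI6 up 9.24-fold. Of 40 mitosis genes, 39 fell and 1 rose (median -1.11), with the proliferation marker MKI67 lower by 3.50-fold and the topoisomerase TOP2A by 3.90-fold.

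There were 3962 higher and 3991 lower genes among 11864 tested (edgeR, adjusted p below 0.05), of which 1054 and 860 changed at least 2-fold. The groups did not overlap for 71.0% of genes, against 10% by chance. As under HL6, more genes were detected in the treated libraries (13327 to 13453 under shDHODH, against 12706 to 12970 under shNT). TMEM40 and CPA4, without a count under shNT, were at least 275-fold and 124-fold higher. SLAMF7, a surface receptor, was at 28.9 CPM against 0.0495 (9.09 ± 0.29), and ANKRD1 (8.18 ± 0.30), LY96 (7.80 ± 0.30) and the potassium channel KCNQ3 (7.76 ± 0.37) followed. With 1 to 3 control counts, LCE1B had a ratio of 388 (95% interval 69.2 to 15351), GCNT3 of 384 (68.4 to 15193), LCE1F of 343 (61.2 to 13606) and PDE6G of 258 (87.9 to 1253). The carbonic anhydrase CA9, a hypoxia marker, had the largest fall (-5.38 ± 0.27), followed by SLC7A11 (-3.60 ± 0.24), the kinesin KIF18A (-2.62 ± 0.39), DHODH, KIF14 (-2.49 ± 0.26), ETV1 (-2.48 ± 0.21), H2BC9 (-2.42 ± 0.15), the kinetochore gene KNTC1 (-2.37 ± 0.28), ZGRF1 (-2.30 ± 0.45) and GAP43 (-2.28 ± 0.13).

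By camera, 25 of 42 lists passed, 12 up and 13 down. Other splits of the 6 libraries gave up to 21, but they keep part of the treatment contrast. With an estimated correlation 10 lists passed. Besides p53 and interferon (adjusted p = 0.00782 each), those upward were NF-kB (15 of 17 rose, 1 fell, median 1.70; 0.0237), senescence-associated secretion (11 of 13 rose, 1 fell; 0.0324), autophagy and lysosome (23 of 26 rose, 1 fell; 0.0462) and MHC class I (15 of 17 rose; 0.0484). HLA-B rose 6.54-fold, B2M, the light chain of class I molecules, 3.71-fold, and the lysosomal sialidase NEU1 3.26-fold. Those downward were cholesterol synthesis (21 of 24 fell, 2 rose; 0.0237), fatty acid synthesis (10 of 11 fell; 0.0237), mitosis (0.0324) and DNA replication (35 of 39 fell, 1 rose, median -0.86; 0.0484). INSIG1, a sterol sensor, fell 4.72-fold and LPIN1 4.18-fold. Adjusted over the list alone, the counts were the same except for 1 interferon gene that also fell. The lipid lists also fell under HL6 (cholesterol 17 of 24 and 2 rose, fatty acid 10 of 11 and 1 rose). NF-kB (15 of 16 rose, 1 fell), senescence (11 of 13 rose) and MHC class I (10 of 17 rose, 1 fell) rose there too. Autophagy and lysosome rose as well (14 of 26, and 2 fell). All passed camera under HL6 with the preset correlation and none with an estimated one. None of them differed between HL6 and shDHODH past the threshold (camera, adjusted p = 0.0501 to 0.806).

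The ATF4 list went mostly down: 16 of 27 fell and 8 rose, the same counts adjusted over the list alone (median -0.64; adjusted p = 0.392 with an estimated correlation). ATF4 itself was 239 against 543 CPM (-1.19 ± 0.06) and the asparagine synthetase ASNS fell 2.76-fold. Of the 5 genes of de novo pyrimidine synthesis, 4 fell and 1 rose, and the list did not pass (camera, adjusted p = 0.315). UMPS (0.79 ± 0.07) and HEXIM1 (0.76 ± 0.07) rose, as did GPX4 (0.38 ± 0.06), and CAD (-0.18 ± 0.06), MYC (-0.25 ± 0.05) and PIK3CA (-1.06 ± 0.27) fell. The ribosome biogenesis list did not pass (10 rose and 17 fell of 40, median -0.03), nor did heat shock (7 rose and 3 fell of 13). Purine synthesis (10 of 14 fell, 2 rose) and dNTP supply (8 of 14 fell, 4 rose) passed camera only with the preset correlation. So did MYC targets (12 of 20 fell, 2 rose).

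**Figure D2:**
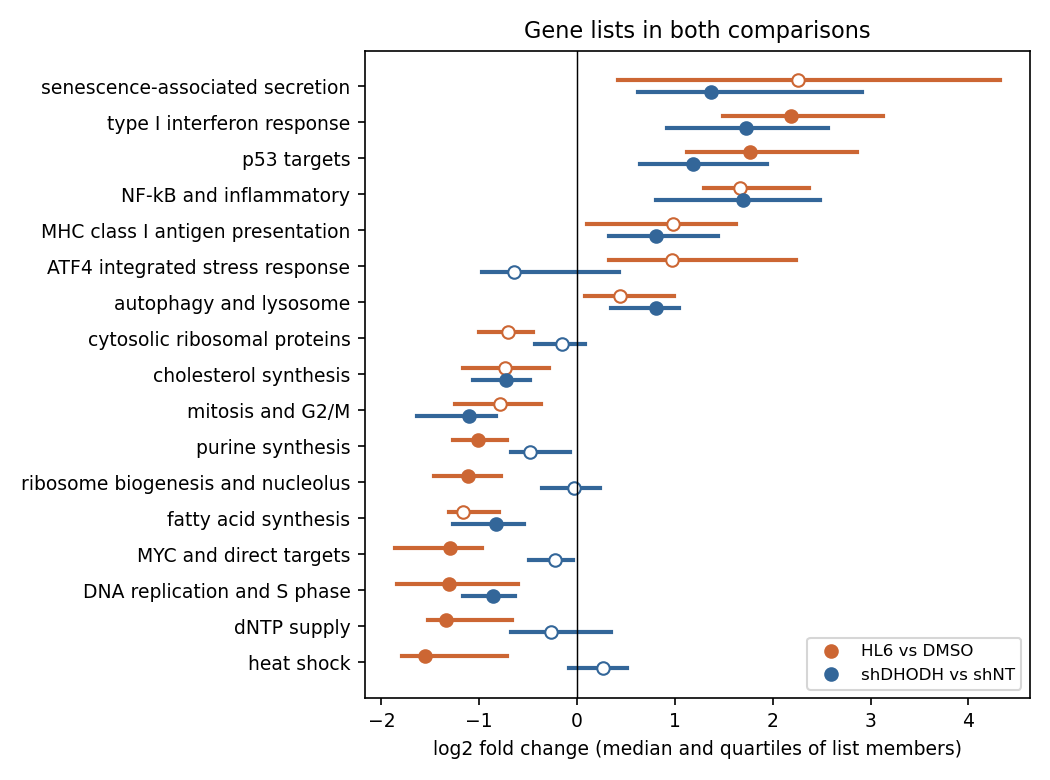
Median log2 fold change of each of 17 lists (points) with the quartiles of its members (lines) under HL6 and shDHODH; filled points passed camera with both the preset and the estimated correlation. Interferon and p53 lists lie above 0 in both comparisons, and ribosome biogenesis has medians of -1.12 and -0.03.

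Across 11672 genes tested in both, which are not independent replicates, the HL6 and shDHODH log2 fold changes correlated with Pearson's r of 0.655 and Spearman's rho of 0.481. The comparisons share no control library. Both called 2006 genes higher, where independent lists would share 1138, and 1849 lower, where they would share 1180. Opposite calls numbered 400 (higher under HL6) and 673 (lower under HL6), where independent lists would share 1157 and 1160.

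**Figure D3:**
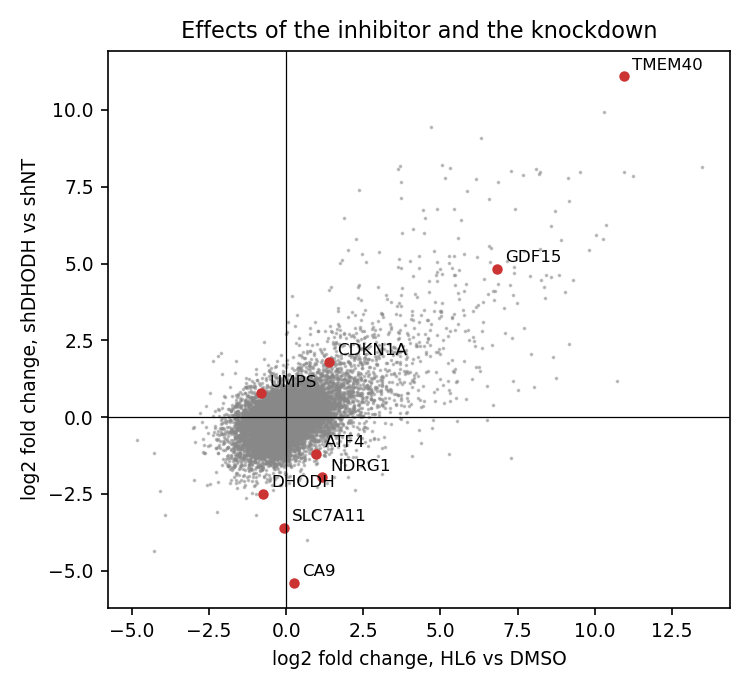
Log2 fold change of each gene under HL6 (horizontal) and shDHODH (vertical), with 9 genes marked. GDF15 rose in both (6.84 and 4.84), and ATF4 rose under HL6 (0.97) and fell under shDHODH (-1.19).

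The difference between the effects was tested on 12282 genes, and 5760 passed (edgeR interaction, adjusted p below 0.05), 2765 higher and 2995 lower under HL6. Among them, 984 were called in opposite directions. The hypoxia- and stress-induced NDRG1 (difference 3.07 ± 0.13), the mTOR inhibitor gene DDIT4 (3.43 ± 0.16), TXNIP (2.79 ± 0.13), the phosphatase PTP4A3 (4.87 ± 0.24) and the interferon regulator IRF7 (3.09 ± 0.16) were higher under HL6. MAT2A, which makes S-adenosylmethionine (-2.54 ± 0.13), the co-chaperonin HSPE1 (-2.50 ± 0.13), SRSF2 (-2.06 ± 0.12), the cold-inducible RBM3 (-2.12 ± 0.12) and H2BC12 (-2.19 ± 0.13) were lower. Of 44 lists, 17 passed and 9 did with an estimated correlation, led by ribosome biogenesis (median difference -1.18; adjusted p = 0.000608 with an estimated correlation). The ATF4 list differed by a median of 1.79, with 23 of 27 genes higher under HL6 and 1 lower (adjusted p = 0.0103 with an estimated correlation). Of 60 splits of the libraries, the real one included, 34 gave 17 or more lists past the preset threshold. The others keep part of the treatment contrasts, so this is no chance level. Kind of perturbation and day label cannot be told apart here.

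**Figure D4:**
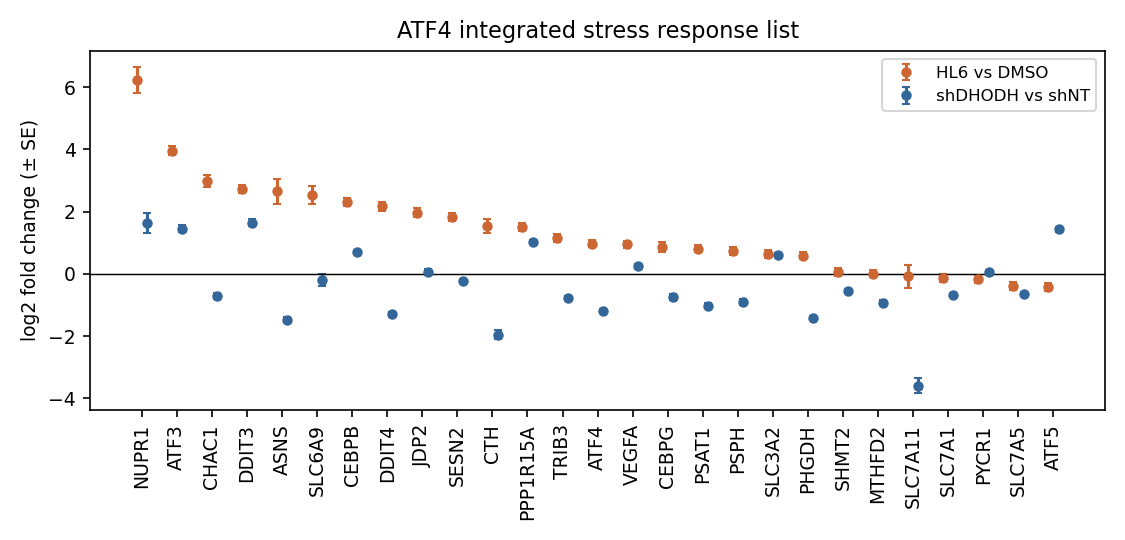
Log2 fold change (± SE) of the 27 tested ATF4 list genes under HL6 and shDHODH. Of these, 20 rose under HL6 and 8 under shDHODH.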

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

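The tests of explanations below were chosen after the results were seen; the counts over other splits of the libraries were planned. No outlier test was made, because every group has 3 libraries.

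The results taken up here are effects that differed between HL6 and shDHODH by the test of the difference itself: 5760 genes, 984 of them in opposite directions, and 17 lists. Of the genes named for it, NDRG1 differed by 3.07 (log2, HL6 minus shDHODH), DDIT4 by 3.43, TXNIP by 2.79, PTP4A3 by 4.87, IRF7 by 3.09, MAT2A by -2.54, HSPE1 by -2.50, SRSF2 by -2.06, RBM3 by -2.12 and H2BC12 by -2.19. Among the genes reported throughout, the values were 1.71 for DHODH, -1.20 for HEXIM1, -1.63 for UMPS, -0.45 for CDKN1A, 1.97 for GDF15, 2.12 for ATF4, 0.54 for GPX4 and 3.49 for SLC7A11. Some control levels differed between the experiments. SLC7A11 had a mean of 1.86 CPM in DMSO and 14.4 in shNT, against 1.72 in HL6 and 1.19 in shDHODH. HSPE1 was at 144 in DMSO and 30.7 in shNT (41.1 in HL6, 49.7 in shDHODH), and PTP4A3 at 0.85 and 14.8 (37.9 and 22.6). NDRG1 (108 in DMSO, 226 in shNT), DDIT4 (14.7, 54.9), TXNIP (65.5, 160), ATF4 (257, 535) and GDF15 (3.76, 7.34) were higher in shNT. UMPS (74.6, 37.1), HEXIM1 (67.4, 38.3) and H2BC12 (43.9, 22.9) were higher in DMSO. The order turned in treated libraries for ATF4 (488 in HL6, 235 in shDHODH), UMPS (41.7, 64.0) and HEXIM1 (49.6, 64.8). Controls were closer for RBM3 (256 in DMSO, 268 in shNT), SRSF2 (307, 264), MAT2A (237, 183) and IRF7 (8.78, 11.8). They were also closer for CDKN1A (295, 268), GPX4 (390, 380) and DHODH (24.6, 24.5). How much control levels add to these differences was not tested. Median differences of the lists were 1.79 for ATF4, -1.61 for heat shock, -1.34 for MYC targets, -1.18 for ribosome biogenesis, 1.15 for FOXO targets, 1.15 for epithelial mesenchymal transition, -0.84 for purine synthesis, 0.79 for Wnt targets and -0.77 for dNTP supply. They were 0.71 for immediate early genes, 0.64 for hypoxia, 0.61 for interferon, -0.53 for ribosomal proteins, -0.51 for respiratory complexes, 0.50 for p53 targets, -0.47 for NRF2 targets and -0.44 for DNA replication. With an estimated correlation 8 of the 17 lists did not pass: FOXO targets (adjusted p = 0.0728), DNA replication (0.184), NRF2 targets (0.226), epithelial mesenchymal transition (0.381), respiratory complexes (0.456), and immediate early genes, Wnt targets and ribosomal proteins (0.466 each).

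Of 60 splits drawn within both experiments, 1, the real one, gave 5760 or more genes, and the highest other gave 4778. That highest other split is among 14 that keep the real groups of 1 experiment, and the 45 that regroup both gave 0. Every other split mixes treated and control libraries in at least 1 experiment, which also breaks the effects themselves. The splits therefore cannot exclude chance for a difference between the effects. For lists, 34 of the 60 gave 17 or more, up to 32. The other splits keep part of the treatment contrasts, so they give no chance level for lists. No conclusion is drawn from the number of lists past the preset threshold. For the correlation of 0.655, 1 of 100 splits, the real one, was as large, and the highest other was 0.612. Within each comparison the 10 splits are too few for a share under 0.05. The real splits gave 7944 genes for HL6 and 7953 for shDHODH, 3812 and 1914 of them at least 2-fold, and no other split gave any (0 each); the real split was the 1 of 10 with the most. For lists the real values were 31 and 25 and the highest others 28 and 21, from splits that again keep part of the treatment contrast.

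Of 27 ATF4 list genes, 20 rose under HL6 and 16 fell under shDHODH, although with an estimated correlation the list passed in neither comparison (adjusted p = 0.0768 and 0.392), only in the difference (0.0103). Scaling is argued against: with RLE size factors the median difference was 1.84, and with TMM it was 1.78 above that of all genes. A higher starting level in the shNT controls may account for part of it, since the list stood 0.64 higher in shNT than in DMSO relative to all genes, with 23 of 27 genes above them. The list was also lower in shDHODH than in HL6, by a median of -0.80 relative to all genes, but both values compare tables of different annotation and day label, so how large that part is stays open. Day label, time and kind of perturbation stay open and cannot be told apart, because 0 day labels hold libraries of both comparisons.

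Ribosome biogenesis genes fell under HL6 and had a median near 0 under shDHODH. A scaling error, which moves all genes alike, is argued against by a list median -1.14 from that of all genes. For this list, a uniformly weaker knockdown effect as the whole cause is argued against too, since it would leave residuals near 0. The shDHODH effect was predicted as 0.46 of the HL6 effect, and residuals were centred on their mean over all genes. The list's median residual was then 0.48 (0.443 to 0.502 with 1 library left out). Because the list was picked for this pattern, the residual largely restates it and is not independent evidence. Day label, time and kind of perturbation again cannot be told apart, with 0 shared day labels, and a different biological response to inhibition and depletion was not tested.

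Under HL6, 3166 genes with no count in any DMSO library gained counts, against 680 in the other direction. Larger raw depth is argued against, since the mean HL6 total differed from the mean DMSO total by -668377 counts, with a pooled SD of 345003 within the groups. TMM factors, however, were 1.03 to 1.08 in HL6 and 0.896 to 0.983 in DMSO. On the TMM scale the HL6 libraries were the larger ones, and depth on that scale was not tested. An even background such as genomic DNA cannot be told apart from expression: the 10% of these genes with most counts held 72.3% of the counts, between the bounds set for either answer, and 2462 of them had 10 counts or fewer. Of 52 of these genes tested in the knockdown, 75% rose under shDHODH, against a median of 76.9% in random sets matched on shNT level. That lies within the sets' spread, so although it met the bound set against a shared response, that bound was too loose to decide and this stays open. Genes with almost no shNT counts also passed the count filter only through shDHODH, which fixes their direction in both shares. The rest of the 3166 genes were not covered.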

How the results depend on the processing

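Kept directions and sides of the threshold were the rule: under the alternatives, 164 values of the main results stayed the same and 6 moved. Here the same means within 1.5 times for counts, the same sign and side of the threshold for DHODH, and within a jackknife SD over the 12 libraries, 0.0308, for the correlation. For named genes 3686 stayed the same, 11 lost their call, 5 gained one and 8 reversed; for lists 865, 48, 36 and 8. With an estimated correlation 8 lists passed under HL6 and 10 under shDHODH; the cause was not tested. With HL6 replicate 1 alone, 2758 genes were higher and 1965 lower, with fewer libraries; the spread then comes from the 3 DMSO libraries, and the lone HL6 library is assumed to vary like them. Spearman's rho was 0.481 and Pearson's r without the filter 0.541, while r with the filter of 1 CPM, 0.626, lay just inside its tolerance; the cause was not tested. In 1 fit over all 12 libraries, on genes that both tables hold, 3914 genes were higher and 4132 lower for HL6, which turns the balance between directions, and 3545 and 3297 for shDHODH; the cause was not tested.

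Leaving out 1 library at a time gave 3853 to 4774 higher and 3091 to 4266 lower genes for HL6 (2543 to 2814 and 1191 to 1549 at least 2-fold), 31 to 32 lists and a DHODH change of -0.86 to -0.66. For shDHODH it gave 3645 to 4028 and 3597 to 4085 genes (1047 to 1139 and 693 to 1096), 23 to 26 lists and -2.68 to -2.34. The difference count was 5173 to 6420 and the correlation 0.635 to 0.669.

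Deviations of same-numbered libraries correlated at -0.28, 0.07 and -0.07 in the inhibitor experiment, where 1 of 6 libraries correlated best with its own number. In the knockdown the values were 0.15, 0.002 and 0.12, and 5 of 6 did, a hint of pairing from the data, not the design. With a replicate block, 4091 genes were higher and 3435 lower for HL6, 4131 and 4184 for shDHODH, and 5660 differed.

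Values that reversed had adjusted p-values from 0.261 to 1, none past the threshold. SLC7A11 under HL6 ranged from -0.54 to 0.15 with 1 library left out, and was 0.02 without DMSO replicate 2 and 0.07 without HL6 replicate 2. TIE1 under shDHODH was -0.0033 without the filter and ranged from -0.37 to 0.66 with 1 library left out (-0.10 without shNT replicate 1, -0.18 without shDHODH replicate 2), and EGFL7 from -0.0887 to 0.038. Among lists the direction of camera, not always the sign of the median, turned with 1 library left out. Medians then ranged from -0.20 to -0.033 for UDP-sugar, from 0.061 to 0.22 for mitochondrially encoded mRNAs, from 0.83 to 1.18 for neuroendocrine markers (0.92 without shNT replicate 1) and from -0.00808 to 0.053 for the unfolded protein response. With fry it turned for NRF2 targets (-0.26), transcription elongation (-0.070) and UDP-sugar (-0.11) under HL6 and the unfolded protein response (0.029) under shDHODH. The cause was not tested. Alternatives added after seeing the data changed little: without mitochondrially encoded mRNAs 4275 and 3668 genes were called for HL6, and over the genes that both tables hold there were 3837 and 3325 for HL6 and 3949 and 3979 for shDHODH. Depth limits genes with few control counts to bounds or wide intervals.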

Other observations

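The gene families here were picked after named members had been seen, so the tests, all chosen after the results were seen, used only members not named before. Small nucleolar RNA host genes fell under HL6: of 25 tested, 15 fell and 3 rose, and the 23 not named before had a median log2 fold change of -0.78 (-0.79 with RLE), at percentile 0.01 of 10000 random lists matched on expression. No such gene was tested in the knockdown. SR splicing factors fell in 9 of 11 cases under HL6, and the 9 not named before had a median of -0.92 (percentile 0.15). Under shDHODH 8 of 11 fell and 2 rose, and the same 9 had a median of -0.42 (percentile 2.08). With SRSF1 and SRSF2 included that percentile was 3.69, inside the range of random lists, so the shDHODH result rests on which members are counted. Leaving out named members was itself decided after the values with all members had been seen.

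All 4 tested late cornified envelope genes (LCE1B, LCE1C, LCE1E and LCE1F) rose in both comparisons, a family of near-identical members that was not tested because LCE1B and LCE1F drew attention to it. Histone genes, uncertain as a multigene family, had a median of 0.053 under HL6, inside the random range (percentile 15.2), and of 0.52 under shDHODH (percentile 98.3), where 19 of 46 rose and 11 fell.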
